A study of Mus musculus with 2 samples.

How the data were processed

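Single-cell suspensions of mouse kidney were captured in droplets with barcoded beads, per the labels' protocols, for 1 control and 1 FA sample, both labelled wild type. The deposited matrix pools both samples and holds UMI counts, 21855 genes by 28678 barcodes; every value was checked to be whole and none is below 0. The submitters' processing notes name Seurat and the mm10 build; the aligner, the counting tool and their versions are not given in the sources used here. Barcodes were given to samples by the start of their names. The start C3 was taken as control because the other start, FA3, names the FA sample, which rests on a letter and not on a stated key.

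In each library, every gene above 0 had UMIs in at least 10 barcodes, so a gene listed at 0 was seen in fewer barcodes or was not in that library's annotation. The 2 libraries carried different gene name versions: 1255 names were above 0 in control only and 2543 in FA only. This was found in the file, and the names were then joined, a step chosen after the data were seen. Through synonyms in the RefSeq table of assembly GRCm38.p6, 230 pairs of names were joined, which left 1025 and 2313 names in 1 library only, with 0.283% and 0.315% of UMIs. Genes listed at 0 throughout a library were given no fold and no rank. That departs from the rule fixed before the data were examined, which set any 0 to 3 counts; the rule was kept for a 0 within a class when the gene was above 0 elsewhere in that library.

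Cells with at least 200 genes, at least 500 UMIs and a mitochondrial share of at most 50% were kept, 6295 in control and 15922 in FA; 34.9% of control and 15.7% of FA barcodes exceeded that share. Likely doublets were scored by a rewritten version of Scrublet's scheme of simulated pairs, not by the package itself, and the top cells were left out at 0.8% per 1000 barcodes, 488 in control and 2420 in FA. Both libraries were clustered together on log values of counts per 10000 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, without integration. Variable genes were limited to those above 0 in both libraries that are not mitochondrial, sex-linked or ribosomal RNA. This limit was set after a first clustering on every name had divided almost wholly by library, and the clustering was then run again. The 34 clusters were named from markers fixed before the data were examined. A cluster stayed unnamed with fewer than 3 markers detected in 5% of cells, with leading genes of another class, with low UMIs, or with a score under 1 and no marker among its top 25 genes; the score, top-gene and detection thresholds were set after the clusters had been seen. That left 5 clusters unnamed.

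UMIs were summed per library and class and scaled to CPM, counts relative to the summed total of that library or class. Ratios are FA over control, with exact conditional binomial intervals; sums have exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95%. Classes with at least 50 cells in each library were compared, 10 in all. A list member was measured with 20 or more UMIs over both libraries and counted higher or lower at a ratio of 1.5 or its inverse. A list's median was set against 10000 random lists matched on expression in 20 bins, as a percentile that describes these libraries. Named genes were fixed by size before the data were examined. They were the 10 highest and 10 lowest ratios of the whole library and of proximal tubule-like cells, and 5 and 5 of each other class, at 100 CPM or more and, within a class, 50 UMIs or more in the higher library. Within a class, genes below 10% of the highest class and markers of other classes were left out; every gasdermin and up to 4 members per list were added. Of the genes ranked in B cell-like cells, 1 is not reported here. Mitochondrial, ribosomal protein, haemoglobin, numbered predicted and sex-linked genes were not ranked. The cytotoxic lymphocyte list in T cell-like cells and the MHC class I list in the compared classes were chosen after values were seen. The Casp1 ratio within macrophage-like cells, the genes of the sex comparison, the genes that differed alike in every class and the choice of which lists are given outside the whole library and proximal tubule-like cells (inflammasome and pyroptosis, tubular injury, MHC class II, mitochondrially encoded and nuclear-encoded oxidative phosphorylation, and 6 further lists in B cell-like cells) were made after values were seen.

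Counts were simulated for the proximal tubule-like class over 12611 genes, as Poisson draws from its control profile, so they hold counting error only. Simulated ratios and intervals were scaled by the known change of the total, a correction that the real data did not receive. The median ratio was 4.05 for a true 4-fold change and 1.98 for a true 2-fold change, each with 98% of genes in the interval. For a true ratio of 0.25 it was 0.251, with 94% of genes in the interval. Unchanged genes had a median of 0.998 with 96.7% in the interval. Alternatives were TMM factors, totals without mitochondrial and haemoglobin genes, every barcode, a stricter filter (500 genes, 1000 UMIs, 20% mitochondrial), doublets kept, means over cells, count minimums of 100 and 1, resolutions 0.5 and 2, 4000 variable genes, removal of 10% of counts as free RNA, and unthinned shares. Clustering on every name and a widened proximal tubule class were added after the data were seen. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, igraph 0.11.9, leidenalg 0.10.2, R 4.3.3 and edgeR 4.0.16 (for TMM factors) were used.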

Results

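Droplet single-cell RNA sequencing was done on kidney of wild-type mice, with 1 control library and 1 library of kidney injured with folic acid (FA), a vitamin that harms kidney tubules at high dose. The number of animals behind each library is not given in the sources used here. The series concerns the gasdermins GSDMD and GSDME, pore-forming proteins of lytic cell death, in that injury. Dose and time after FA are not given in the sources used here. The control library held 9681 barcodes and 63646459 UMIs (median 4935 UMIs per barcode), and the FA library held 18997 barcodes and 84138607 UMIs (median 2768). After filtering, 5807 control and 13502 FA cells were kept, with medians of 4827 and 2920 UMIs. With 1 library per group there is no replicate check: no test was run, intervals are 95% and cover counting error only, and every difference is between these 2 libraries. The libraries also differed in sex-linked genes. Xist, expressed from the inactive X chromosome, had 15 UMIs in control and 104149 in FA over every deposited barcode, whereas the Y-linked gene Ddx3y had 3928 UMIs in control and was listed at 0 in FA, so treatment and this difference coincide. The Y-linked genes Eif2s3y, Kdm5d and Uty also had UMIs in control and were listed at 0 in FA. This is the pattern of a male control and a female FA library, so sex and treatment cannot be told apart.

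The first comparison asked which cell classes made up each library. Immune-like cells formed 29.5% of control cells (Clopper-Pearson interval 28.3 to 30.7) and 50.02% of FA cells (49.2 to 50.9). These shares, and those of immune-like cells alone, leave out the unnamed cluster 5, with 16 control and 980 FA cells (7.26% of FA). Its leading genes included Slfn4, Fyb and Tnf, and no marker of its nearest class, erythroid, was detected, so its cell type is open. Neutrophil-like cells were 1 of 5807 in control and 413 of 13502 (3.06%, 2.77 to 3.36) in FA. Monocyte-like cells were 1.02% (0.774 to 1.31) and 4.24% (3.91 to 4.60), NK cell-like cells 0.689% (0.493 to 0.937) and 3.61% (3.30 to 3.94), dendritic-like cells 1.67% (1.36 to 2.03) and 5.28% (4.91 to 5.67), and T cell-like cells 9.52% (8.78 to 10.3) and 16.9% (16.3 to 17.6). Macrophage-like cells were 12.1% (11.3 to 12.96) and 12.6% (12.1 to 13.2), and B cell-like cells 3.44% (2.99 to 3.95) and 3.46% (3.16 to 3.78), so neither share of all cells differed beyond counting error in the main setting. The macrophage-like shares did not stay alike, at 14.9% of control and 19.1% of FA with the stricter filter, 7.83% and 10.1% without a cell filter and 11.99% and 8.87% at resolution 0.5. Of immune-like cells alone, macrophage-like cells were 41.03% (38.7 to 43.4) and 25.3% (24.2 to 26.3), B cell-like cells 11.7% (10.2 to 13.3) and 6.91% (6.32 to 7.55), and T cell-like cells 32.3% (30.1 to 34.6) and 33.8% (32.7 to 34.96).

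Shares of the kidney classes are also given of all kept cells. Proximal tubule-like cells were 37.9% of control (36.7 to 39.2) and 4.21% of FA (3.88 to 4.57). Injured tubule-like cells, named from markers such as Havcr1 (kidney injury molecule 1) and Krt20, were 3 of 5807 in control and 9.58% of FA (9.09 to 10.1). Of these FA cells, 325 lay in cluster 22, led by Vcam1, Cxcl1, Havcr1 and Krt20, and 969 in cluster 6, led by tubule metabolic genes such as Fabp1, Gsta2 and Pck1 with no injury marker among its 10 leading genes. Endothelial-like cells were 16.4% of control (15.4 to 17.4) and 27 of 13502 cells of FA (0.132% to 0.291%). Distal convoluted tubule-like cells, in a cluster that also carried the collecting duct genes Aqp2 and Hsd11b2, were 4.15% (3.65 to 4.70) and 0.0444% (0.0163 to 0.0967). Thick ascending limb-like cells were 1.36% of control (1.08 to 1.69) and 0 of 13502 in FA, for which a floor of 3 counts allows up to 0.0222%. Podocyte-like cells were 1.33% (1.05 to 1.65) and 6.47% (6.06 to 6.89), intercalated-like cells 2.67% (2.27 to 3.12) and 1.63% (1.42 to 1.86), and stromal-like cells 3.27% (2.83 to 3.76) and 1.09% (0.921 to 1.28). Of cells neither immune-like nor unnamed, proximal tubule-like cells were 55.96% and 17.7%, intercalated-like cells 3.94% (3.35 to 4.59) and 6.85% (5.998 to 7.78), the other way, and stromal-like cells 4.83% (4.18 to 5.54) and 4.58% (3.88 to 5.36), with overlapping intervals. Plasma cell-like and urothelial-like cells were 1.02% and 0.654% of control and 0.815% and 0.570% of FA. Unnamed clusters held 2.74% of control cells and 26.2% of FA cells, the largest share of FA, and their cells in FA had a median of 1339 UMIs. A naming threshold set after the data were seen kept 2 of these clusters, with 1203 and 1043 FA cells, out of the injured tubule-like and proximal tubule-like classes that they scored nearest to. Cluster 21, with 61 control and 308 FA cells, scored nearest to thin limb and stayed unnamed. Its leading genes included the injured tubule markers Lcn2 and Dcdc2a. The injured tubule-like counts in both libraries, 3 cells in control among them, thus depend on naming. The FA share of proximal tubule-like cells also moved with the settings, to 9.83% with Leiden resolution 0.5 and 0.0158% without a cell filter, and that of injured tubule-like cells was 20.6% at resolution 0.5 and 2.55% at resolution 2. The FA share of endothelial-like cells was 1.03% with likely doublets kept, against 17.4% of control in that setting, and the control share of thick ascending limb-like cells ranged from 0% to 4.80% over the settings.

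**Figure D1:**
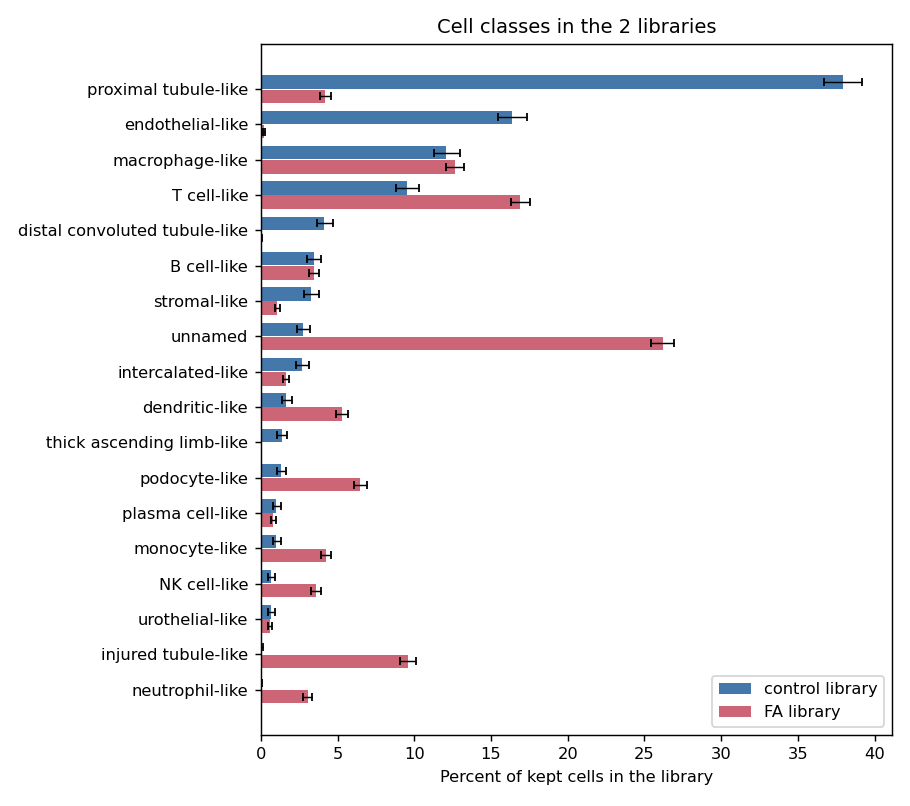
Percent of kept cells (x axis) in each cell class (y axis) in the control library and the FA library, with 95% Clopper-Pearson intervals as error bars. Proximal tubule-like cells are 37.9% of control and 4.21% of FA, and unnamed clusters hold 26.2% of FA.

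Gasdermin genes were examined in each library and class, since the series concerns them. Over the whole library, Gsdmd stood at 15.5 CPM in control (Poisson interval 14.3 to 16.8) and 31.9 in FA (30.5 to 33.4), a ratio of 2.06 (1.88 to 2.25). Gsdme stood at 8.596 CPM (7.71 to 9.55) and 14.7 (13.7 to 15.7), a ratio of 1.71 (1.503 to 1.94). Gsdmc2 had 4.71 and 3.53 CPM and Gsdmc3 1.20 and 1.53 CPM, and the Gsdmc2 ratio lay above 1 instead of below it without a cell filter, with the stricter filter and with doublets kept. Gsdma and Gsdmc4 were listed at 0 in control and had 11 UMIs each in FA.

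Among classes of at least 20 cells, Gsdmd was highest in monocyte-like cells, at 79.4 CPM in control and 70.3 in FA, while plasma cell-like cells had 3.08 and 6.46. In macrophage-like cells it was 50.8 CPM in control (44.3 to 58.0) and 52.0 in FA (48.3 to 56.0), a ratio of 1.02 (0.878 to 1.20). The Gsdmd ratio was 0.886 (0.614 to 1.32) in monocyte-like, 1.25 (0.877 to 1.83) in dendritic-like, 0.733 (0.541 to 1.01) in T cell-like, 0.982 (0.491 to 2.04) in B cell-like and 0.862 (0.584 to 1.31) in podocyte-like cells. None of these 6 ratios differed from 1 beyond counting error, so the 2.06-fold difference of the whole library was not detectable within these classes. Proximal tubule-like cells had 8 Gsdmd UMIs in control (0.442 CPM, 0.191 to 0.872) and 6 in FA (2.66 CPM, 0.975 to 5.78), and the Gsdmd log2 ratio in proximal tubule-like cells was 2.59 (0.78 to 4.30), 1.46 with doublets kept and 3.66 in the widened class. These CPM values, and that of injured tubule-like cells in FA at 7.28 CPM (5.33 to 9.71), lay below the 23.5 CPM of FA B cell-like cells. B cell-like cells had a similar 23.9 CPM in control (13.1 to 40.1), so this comparison does not show whether the tubule values are free RNA.

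Among classes of at least 20 cells, Gsdme was highest in neutrophil-like cells of FA, at 88.1 CPM (68.1 to 112), followed by injured tubule-like cells of FA, at 39.2 CPM (34.5 to 44.4), a class of which 969 of 1294 cells lie in cluster 6, with no injury marker among its leading genes. Proximal tubule-like cells had 10.95 CPM in control (9.48 to 12.6) and 23.9 in FA (18.0 to 31.2), a ratio of 2.18 (1.585 to 2.96). Gsdme ratios were 0.867 (0.617 to 1.24) in macrophage-like and 1.18 (0.635 to 2.36) in T cell-like cells. B cell-like cells, used as a gauge of free RNA, also had more Gsdme in FA: 2 UMIs (3.42 CPM, 0.414 to 12.3) in control and 16 UMIs (15.03 CPM, 8.59 to 24.4) in FA. With each cell thinned to 1000 UMIs, 1.15% of control (0.737 to 1.70) and 3.02% of FA (1.77 to 4.80) proximal tubule-like cells had a Gsdme UMI, against 0% (Clopper-Pearson upper bound 1.90) and 1.56% (0.628 to 3.18) of B cell-like cells. Thinning left out 114 and 7 proximal tubule-like and 8 and 17 B cell-like cells, and the unthinned shares were 8.31% and 9.14% against 1% and 2.998%. Median depths were 6565 and 3488 UMIs in proximal tubule-like cells and 2434 and 1964 in B cell-like cells. The FA intervals of proximal tubule-like and B cell-like cells overlapped, so the share in FA proximal tubule-like cells was not separated from that of B cell-like cells. Thinned shares in FA T cell-like (0.999%, 0.619 to 1.52) and NK cell-like cells (0.425%, 0.0515 to 1.53) lay below the proximal tubule-like interval. That of FA dendritic-like cells (0.983%, 0.396 to 2.02) overlapped it, so the outcome depends on the class taken as background. The thinned share in injured tubule-like cells of FA, 3.96% (2.87 to 5.31), also overlapped that of FA B cell-like cells but lay above those of T cell-like, NK cell-like and dendritic-like cells. The 39.2 CPM of injured tubule-like cells lay above the interval of FA B cell-like cells. The thinned share in neutrophil-like cells, 9.04% (6.34 to 12.4), lay above that of FA B cell-like cells. Unthinned shares in injured tubule-like and neutrophil-like cells of FA were 15.8% and 14.8%, at median depths of 3971 and 1677 UMIs, and thinning left out 233 and 37 cells.

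**Figure D2:**
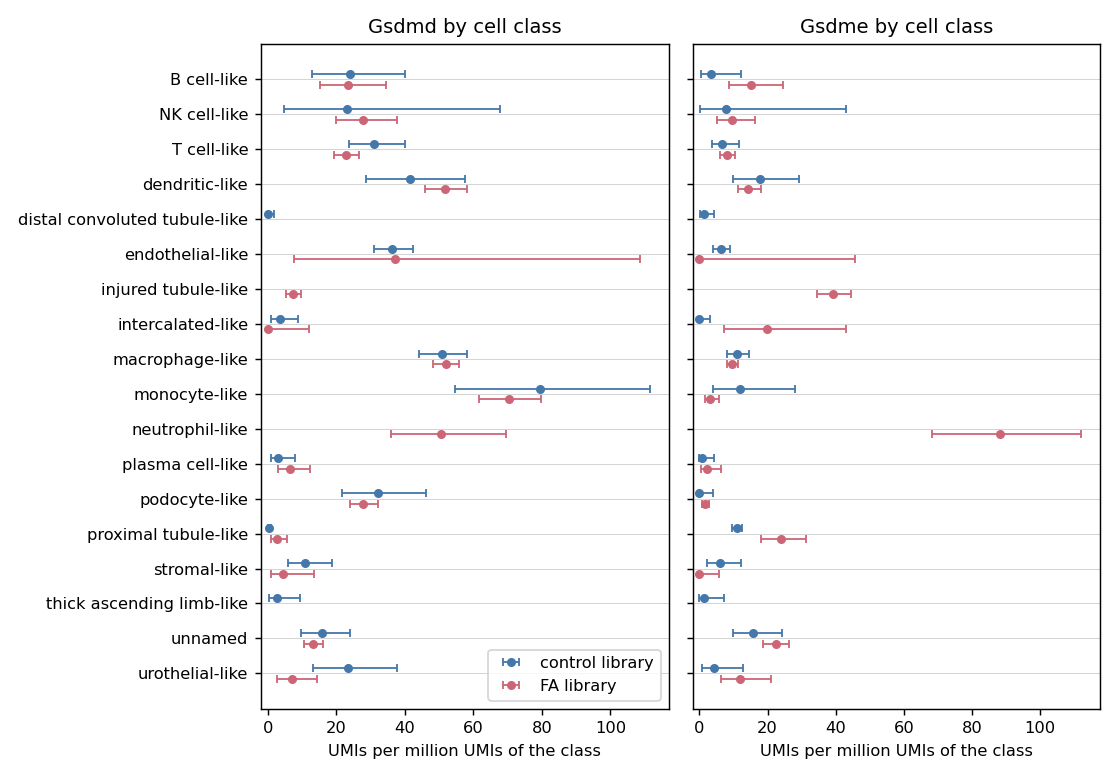
Gsdmd and Gsdme in CPM of the class (x axes) in each cell class with at least 20 cells in the library (y axis), with 95% Poisson intervals as error bars. Gsdmd is 50.8 in control and 52.0 in FA macrophage-like cells, and Gsdme reaches 88.1 in FA neutrophil-like cells.

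Summed over all kept cells, the FA library had higher levels of inflammatory genes and lower levels of tubule and endothelial genes. The 10 highest ratios belonged to the monocyte chemoattractants Ccl7 (ratio 188, interval 146 to 246), Ccl2 (33.1) and Ccl12 (25.7), the neutrophil-attracting chemokine Cxcl2 (54.5), the neutrophil calcium-binding proteins S100a9 (144) and S100a8 (129), the complement factor properdin Cfp (24.2), the histone gene H2ac8 (27.8), AA467197 (31.4) and the mitochondrial import gene Timm23 (38.1). The 10 lowest belonged to the androgen-regulated proximal tubule gene Kap (2483 CPM in control and 2.52 in FA), the methyltransferase Inmt (207 and 0.348), Dnase1 (419 and 5.79), Igfbp3 (203 and 2.75) and the endothelial genes Esm1 (262 and 1.39), Gpihbp1 (108 and 0.696), Ptprb (195 and 1.41), Emcn (337 and 2.87), Plvap (302 and 3.93) and Flt1 (291 and 4.12). Timm23 was at least 2-fold higher and the ubiquitin-conjugating enzyme Ube2s at least 2-fold lower in all 10 compared classes. The libraries carried different gene name versions, and whether annotation gives these 2 differences, or those of Mir6236 and Tmem254a, which were also at least 2-fold higher in every compared class, was not tested.

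The gene lists followed the same division. Of 19 measured genes of the inflammasome and pyroptosis list, 15 were at least 1.5-fold higher in FA and 0 lower (median log2 ratio 1.14, percentile 100 of matched random lists). Within classes the same list had 7 higher and 2 lower of 18 in macrophage-like (median 0.35), 4 and 2 of 18 in monocyte-like (0.25) and 4 and 5 of 18 in dendritic-like cells (0.03), but 7 and 0 of 8 in intercalated-like cells (1.11, percentile 99.8). Immune-like cells were 29.5% of control and 50.02% of FA. Nlrp3, the inflammasome sensor, had a ratio of 11.4 (9.97 to 13.2), Mefv 11.01, the cytotoxic protease Gzmb 8.13 and the cytokine Il1b 5.96 (5.81 to 6.11). Necroptosis genes were higher for 6 of 8 (median 0.90), with Zbp1 at 6.16 and Ripk3 at 4.21, and apoptosis genes for 7 of 15 (median 0.47), with 2 lower. Chemokines and cytokines were higher for 19 of 26 (median 1.89), NF-kB targets for 14 of 16 (1.65), interferon-stimulated genes for 17 of 22 (1.47), complement and acute phase genes for 7 of 13 (1.02), and neutrophil granule genes for 14 of 15 (2.16). Cytotoxic lymphocyte genes were higher for 10 of 11 (1.42), alternative macrophage genes for 10 of 14 (1.25), MHC class I genes for 7 of 10 (0.77), cell cycle genes for 23 of 24 (2.91), p53 and arrest genes for 7 of 14 (0.55), unfolded protein response genes for 10 of 16 (0.84), and immediate early and dissociation stress genes for 20 of 23 (1.28). With each cell weighed the same, the chemokine and cell cycle medians were 1.27 and 2.02, and the latter was 2.11 with doublets kept. Mki67, a proliferation marker, had a ratio of 14.3 and the arrest gene Cdkn1a 11.7. Within T cell-like cells, cytotoxic lymphocyte genes were higher for 2 and lower for 5 of 11 (median -0.45, percentile 0.11). MHC class I genes were higher for 0 of 10 in T cell-like, macrophage-like, monocyte-like and dendritic-like cells, 1 of 10 in podocyte-like and 2 of 10 in B cell-like cells. They were higher for 10 of 10 in proximal tubule-like, 7 of 9 in plasma cell-like, 4 of 7 in intercalated-like and 2 of 9 in stromal-like cells.

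The lists lower in FA were those of tubule, endothelium and mitochondria. Of 31 proximal tubule transport and enzyme genes, 29 were lower (median log2 ratio -2.09, percentile 0), as were 19 of 20 distal transport genes (median -3.98), with the thiazide-sensitive cotransporter Slc12a3 at 451 CPM in control and 8.42 in FA. Endothelial adhesion genes were lower for 12 of 15 (-2.22), nuclear-encoded oxidative phosphorylation genes for 29 of 37 (-0.77), mitochondrially encoded genes for 11 of 13 (-1.85) and folate handling genes for 12 of 23 (-0.91), with the folate receptor Folr1 at 203 and 47.4 CPM. The nuclear-encoded list was lower for all 37 genes in proximal tubule-like cells. It was higher for 24 and lower for 0 of 37 in macrophage-like cells (median 0.73), and 36 of 37 were neither in T cell-like and B cell-like cells. With each cell weighed the same, the medians of the proximal tubule transport, mitochondrially encoded and folate handling lists were -1.23, -0.88 and -0.31. Without a cell filter those of the distal transport and folate handling lists were -1.71 and -0.12, and with doublets kept the distal transport median was -2.09. Mitochondrially encoded genes were also lower, at percentile 0, in the 9 compared classes other than proximal tubule-like cells. Their medians were -3.01 in dendritic-like, -2.84 in plasma cell-like, -2.44 in macrophage-like, -2.39 in intercalated-like, -1.66 in monocyte-like, -1.63 in T cell-like, -1.44 in podocyte-like, -1.11 in stromal-like and -0.99 in B cell-like cells. In proximal tubule-like cells 3 were higher and 6 lower of 13 (median -0.37, percentile 84.5), and the median was 0.28 at resolution 0.5. With the stricter filter, which also lowers the mitochondrial share allowed, the medians were -1.52 in dendritic-like, -1.44 in macrophage-like, -0.72 in podocyte-like, -0.68 in T cell-like, -0.30 in stromal-like and -3.24 in intercalated-like cells, and with free RNA removed they were -0.32 in monocyte-like, -4.06 in dendritic-like and -3.83 in plasma cell-like cells. Without a cell filter they were -1.83 in B cell-like, -2.25 in T cell-like and -1.71 in stromal-like cells. Mitochondrial genes held 12.5% of kept UMIs in control and 4.63% in FA. Within those 9 classes, the median mitochondrial share per cell was higher in FA in T cell-like (0.996% and 1.72%) and dendritic-like cells (0.322% and 0.707%). It was also higher in macrophage-like, monocyte-like, plasma cell-like, stromal-like and B cell-like cells, and lower in intercalated-like cells (13.7% and 0.540%). Podocyte-like cells had 1.13% in both libraries. The list medians come from summed UMIs and so do not describe the median cell. Fatty acid oxidation genes were lower for 12 and higher for 7 of 31 (median -0.39), and that median was 0.14 without a cell filter. Genes of ferroptosis and iron (5 higher and 5 lower of 17, median -0.20), glycolysis (4 and 4 of 17, -0.15), hypoxia (5 and 6 of 13, -0.01), extracellular matrix (8 and 7 of 22, -0.37) and MHC class II (0 and 3 of 8, -0.18) went both ways or moved little, and the extracellular matrix median was 1.19 without a cell filter and 0.78 with doublets kept, and the MHC class II median -0.81 with each cell weighed the same. Of 26 measured tubular injury genes, 17 were higher and 1 lower (median 1.51), with Krt20 at a ratio of 82.4, Timp1 at 32.4 and the injury marker Lcn2 at 18.5. Havcr1 was listed at 0 in control, so it has no fold, and had 44.8 CPM in FA.

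Proximal tubule-like cells were then compared between libraries, 2203 in control (clusters 3, 16, 23 and 26) and 569 in FA (cluster 15). The highest ratios were those of Wfdc2 (136, 101 to 189), complement C3 (38.6), the fatty acid hydroxylase Cyp4a14 (32.9), osteopontin Spp1 (30.05), the fibrinogen chains Fgg (27.9), Fgb (27.4) and Fga (19.6), Tmem254a (24.0), Wsb1 (20.7) and Slc25a25 (15.4). The lowest were Kap (5481 CPM in control and 0.886 in FA, where it had 2 UMIs; ratio 0.000162, interval 1.96e-05 to 0.000584), Inmt (437 and 1.33, 3 UMIs; ratio 0.00304, 0.000627 to 0.00889), Cyp2d12 (116 and 2.66), Ube2s (138 and 4.43), Dnase1 (913 and 61.1), Dnajc12 (364 and 25.2), the urea cycle enzyme Ass1 (3332 and 238), the cyclin Ccnd1 (417 and 31.4), Ak4 (140 and 15.5) and Clec2h (301 and 33.7). Cyp4a14 led cluster 15, Dnase1 and Clec2h cluster 3, Ass1 and Dnajc12 cluster 16 and Kap cluster 23, so several of these genes also set the clusters apart that hold the class in each library. Of 24 measured tubular injury genes 20 were higher and 4 lower (median log2 ratio 4.45, percentile 100), and the median ranged from 3.49 with a count minimum of 100 to 5.10 at resolution 0.5. Tubular injury genes also lay at percentile 100 in T cell-like (16 of 23 higher, median 1.91), macrophage-like (18 of 22, 1.63), intercalated-like (13 of 15, 2.20) and B cell-like cells (9 of 16, 1.07). With a count minimum of 100 the T cell-like and B cell-like medians were 0.94 and 0.37, and with 10% of counts removed as free RNA the B cell-like one was 0.23. The macrophage-like median was 2.25 at resolution 0.5, and the intercalated-like one 3.12 with a count minimum of 1, 3.07 without a cell filter and 2.98 with doublets kept. The same genes gained a median of 25.8 CPM in proximal tubule-like cells and 14.2 CPM in B cell-like cells.

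The proximal tubule transport and enzyme list was not lower in this class. Of 31 measured genes 8 were higher, 10 lower and 13 neither, with a median log2 ratio of 0.10 (-0.19 with TMM factors), and the sulphate transporter Slc13a1 (ratio 8.66) and the oxygenase Miox (0.176) were among those that differed most. Slc13a1 was higher in every compared class (log2 ratios 1.73 to 5.50), lymphocyte-like classes included, so its ratio is not particular to proximal tubule-like cells. The class was named by markers that overlap this list, and with injured tubule-like cells and the nearest unnamed clusters added, an alternative chosen after the data were seen, the median was -1.23. All 37 nuclear-encoded oxidative phosphorylation genes were lower (median -1.27, against -0.79 for matched random lists, percentile 0.07; median -0.52 with doublets kept), among them Sdhd at 0.240 and Sdhc at 0.274. Inflammasome and pyroptosis genes stayed near their matched lists, with 4 higher and 1 lower of 10 (median 0.17, percentile 52.9), and their median was -0.12 with TMM factors and 1.90 in the widened class. Interferon-stimulated genes (14 of 18 higher, median 3.19), NF-kB targets (15 of 16, 2.35), chemokines and cytokines (13 of 14, 2.02), complement (8 of 9, 2.32), MHC class I (10 of 10, 1.69), MHC class II (7 of 7, 2.42) and unfolded protein response genes (10 of 13, 1.41) were higher. Apart from the last, these medians moved with the settings. The interferon-stimulated median was 1.71 with a count minimum of 100 and 4.72 in the widened class, and the NF-kB median 1.39 and 3.29 in the same settings. At resolution 0.5 the chemokine and complement medians were 3.01 and 3.30. The MHC class II median was 1.74 with each cell weighed the same, and with 10% of counts removed as free RNA the MHC class II and class I medians were 4.04 and 2.81. Neutrophil granule genes, which mark another cell type, were also higher in proximal tubule-like cells (4 of 5, median 3.51, percentile 100; 2.79 with each cell weighed the same). In B cell-like cells the medians were 3.22 for complement, with 3 genes measured, 1.42 for chemokines, 1.31 for interferon-stimulated genes, 0.64 for NF-kB targets, 0.75 for unfolded protein response genes, -0.05 for MHC class I and -0.65 for MHC class II. With a count minimum of 100 the complement and chemokine medians in B cell-like cells were -0.63 and 0.32, and with a count minimum of 1 they were both 0.14. Hspa5, the endoplasmic reticulum chaperone, had a ratio of 4.96 and Cxcl1 a ratio of 293. Immediate early genes (14 of 23 higher, median 1.27) and cell cycle genes (11 of 20, 0.72) changed direction to medians of -1.86 and -0.36 when 10% of counts were removed as free RNA.

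Macrophage-like cells, in cluster 11 for control and clusters 2 and 18 for FA, had 8 of 8 measured MHC class II genes lower (median log2 ratio -3.73), with H2-Aa at 17308 CPM in control and 946 in FA, H2-Eb1 at 18032 and 990 and the class II regulator Ciita at 257 and 18.8. The interferon-induced chemokine Cxcl9 (204 and 8.16) and the elastase Mmp12 (647 and 49.4) were also lower. Ccl7 (ratio 136), Timm23 (67.1), the histone genes H2ac8 (43.5) and H1f5 (29.3) and Ecm1 (36.0) were highest. H2-Aa, H2-Eb1 and Mmp12 led the control cluster, and Ccl7, H2ac8 and H1f5 led FA cluster 18. Nlrp3 had a ratio of 3.29 (2.79 to 3.89), Casp4 1.97 (1.65 to 2.36) and Casp1 0.715 (0.624 to 0.820) in the same cells. Monocyte-like cells also had lower MHC class II genes (7 of 7, median -2.75), among them H2-Eb1, H2-Aa, H2-Ab1 and Cd74 with ratios from 0.0756 to 0.149, together with Hpgd (0.146). Their highest ratios were those of the acute phase gene Saa3 (319, 57.2 to 12598), Slfn4 (58.6, 16.2 to 485), the metallothionein Mt1 (36.6), Lrg1 (at least 32.1-fold higher) and Ier3 (29.0). Dendritic-like cells had Ifitm1 at least 255-fold and Timm23 at least 33.3-fold higher, with Ffar2 at 35.8 (12.2 to 174), Mir6236 at 35.1 and the cytokine Osm at 23.6, and Hpgd (0.0380), Ube2s (0.0641), Cxcl9 (0.0805), Kctd14 (0.103) and Trf (0.154) lowest.

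Lymphocyte-like and kidney classes were compared in the same way. T cell-like cells had Timm23 (81.5, 27.8 to 396), the stress-response factor Atf3 (9.60), Gadd45g (8.99), Mir6236 (8.83) and Cdkn1a (6.84) highest, and Ube2s (0.111), Lztfl1 (0.269), the integrin Itga1 (0.323), Rcbtb2 (0.326) and Zfp91 (0.333) lowest. B cell-like cells had Mgp (68.7, 12.1 to 2735), Timm23 (22.9, 7.66 to 113), Zfp869 (12.7), Mpp7 (10.2) and Mir6236 (8.997) highest, and Ube2s (0.171), Trim5 (0.243), B3gnt8 (0.298) and Zfp91 (0.328) lowest. Plasma cell-like cells had Timm23 (at least 52.9-fold), Dusp4 (21.4), Ighg2c (16.3), H2ac8 (14.3) and Ctla4 (12.9) higher, and Ighg1 (0.0516), Prg2 (0.120), Vpreb3 (0.279), Ly6d (0.480) and the joining chain Jchain (0.506) lower. Podocyte-like cells had Gadd45g (78.8), Timm23 (35.9, 12.2 to 174), Cebpd (21.2), Tmem176a (15.8) and the cytokine-signalling inhibitor Socs3 (8.76) highest, and the clock-controlled genes Dbp (0.0227) and Per3 (0.114), Ube2s (0.0496), Creg2 (0.131) and Pde10a (0.146) lowest. Stromal-like cells had Tmem254a (59.9, 19.9 to 296), Timp1 (24.7), Fgl2 (11.2), Atf3 (10.1) and Cdkn1a (9.29) highest, and Fbln5 (0.00110, 2.77e-05 to 0.00611), Igfbp3 (0.00227, 0.000275 to 0.00821), Hsd11b1 (0.00643, 0.000777 to 0.0233), Dpep1 (0.00795, 0.000960 to 0.0289) and Dbp (at most 0.0124) lowest. Intercalated-like cells, with a median of 5784 UMIs in control and 1020.5 in FA, had S100a6 (at least 694-fold), the interferon regulator Irf7 (156, 41.7 to 1306), Timm23 (120, 39.9 to 592), Ly6a (50.3) and Psmb8 (33.2) higher. The anion exchanger Slc4a1 (0.0142, 0.00291 to 0.0415), the ammonia transporter Rhcg (0.0357), Slc16a7 (0.0366), Scd2 (0.0412) and Malrd1 (at most 0.0489) were lower in them.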

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

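The clustering on every name and the widened proximal tubule class were chosen after the data were seen; the other settings were fixed before. Of 525 results, none whose interval excluded no change turned direction under TMM factors (442 compared, 346 within their interval), totals without mitochondrial and haemoglobin genes (442, 383), resolution 2 (307, 295), 4000 variable genes (307, 287) or clustering on every name (307, 298). TMM factors shifted log2 ratios by -0.29 in proximal tubule-like, -0.55 in plasma cell-like, -0.23 in intercalated-like, 0.27 in monocyte-like and 0.13 in stromal-like cells, and list medians near 0 changed sign with them, such as 0.10 to -0.19 for transport and enzymes in proximal tubule-like cells. Totals without mitochondrial and haemoglobin genes shifted them by -0.12 in the whole library and -0.18 in intercalated-like cells. Of 130 named gene ratios, 37 moved by over 1.5 times with doublets kept, 30 with cells weighed the same and 24 with the stricter filter; of 110 within classes, 33 did without a cell filter, 26 at resolution 0.5 and 16 with free RNA removed, as did 11 of the 20 of proximal tubule-like cells in the widened class. Where values moved or turned, the cause was not tested. No paired analysis was possible because each group has 1 library. Depth limits the small classes: 27 endothelial-like cells of FA had 80693 UMIs.

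The FA share of proximal tubule-like cells, 4.21%, was 0.0158% without a cell filter, 3.72% with the stricter filter, 6.09% with doublets kept, 9.83% and 4.59% at resolutions 0.5 and 2, and 3.68% with 4000 variable genes. The endothelial-like share of FA was 0.863% without a cell filter, 0% with the stricter filter, 1.03% with doublets kept and 0.119% at resolution 2. The macrophage-like share of FA was 10.1%, 19.1%, 8.87% and 13.8% without a filter, with the stricter filter and at resolutions 0.5 and 2, and the neutrophil-like share 2.53% and 3.55% without a filter and with the stricter filter. The whole-library log2 ratio of Gsdmd was 0.57 with cells weighed the same, 1.26 without a filter, 0.67 with the stricter filter and 0.87 with doublets kept; that of Gsdme was 1.11 with cells weighed the same and 1.22 without a filter. In proximal tubule-like cells, the tubular injury median was 5.10 at resolution 0.5 and the transport and enzyme median -1.23 in the widened class.

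Directions turned as follows. Without a cell filter, the log2 values were 0.14 for fatty acid oxidation in the whole library, -0.039 for MHC class II in intercalated-like cells and 0.67 for Gsdmc2. With doublets kept, MHC class II in intercalated-like cells was -3.08 and Gsdmc2 0.27, and with the stricter filter Gsdmc2 was 0.87 and Ccl5 in proximal tubule-like cells -2.82. With cells weighed the same, MHC class II in intercalated-like cells was -0.47 and Cdkn2a in the whole library -0.22. With 10% of counts removed as free RNA, the tubular injury median in podocyte-like cells was -0.053, and those of the cell cycle and immediate early lists in proximal tubule-like cells -0.36 and -1.86. In that class Cflar was -0.42 at resolution 0.5, and Hmgb1 and Fabp5 were 0.20 and 0.51 in the widened class.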

Other observations

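The tests of immune growth and of doublets for endothelial-like cells and the test of class mix for Gsdmd were chosen only after the result was seen, as were the counts of genes that differed alike in every class.

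In proximal tubule-like cells, p53 and arrest genes were higher in FA for 7 and lower for 2 of 12 measured (median log2 ratio 1.82), with Gadd45b at a ratio of 49.6 and Cdkn1a at 8.01, and that median was 0.28 after removal of 10% of counts as free RNA. Extracellular matrix genes were higher for 8 of 11 (median 2.87, and 3.59 with a count minimum of 1), while glycolysis genes were higher for 3 and lower for 7 of 15 (-0.51), with Hk1 at 32.02 and Pgk1 at 0.308. Folate handling genes were lower for 5 and higher for 1 of 22 (-0.27). The ferritin light chain Ftl1 was at 0.267 and the peroxidase Gpx4, which guards against ferroptosis, at 0.362.

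MHC class II genes were lower in stromal-like (5 of 6, median -4.58), T cell-like (6 of 8, -1.496) and B cell-like cells (6 of 8, -0.65) as well as in macrophage-like cells, while dendritic-like cells (2 lower and 0 higher of 8, -0.26) differed little. In plasma cell-like cells 1 was lower and 1 higher of 5 (median 0.02, percentile 1.015, against 0.70 for matched random lists). The plasma cell-like median was -0.53 with TMM factors, -0.61 without a cell filter, -0.58 with doublets kept and 2.08 with free RNA removed, so it gives no direction. The stromal-like median was -1.40 without a cell filter, -1.46 with doublets kept, -1.96 with free RNA removed and -6.74 with a count minimum of 100. The T cell-like one was -0.67 with cells weighed the same and -0.83 without a cell filter. Macrophage-like cells had H2-Aa at 17308 CPM in control and 946 in FA. Whether free RNA or doublets from them give the stromal-like and T cell-like values was not tested. In intercalated-like cells the median was 1.09 (5 of 5 higher), but -0.47 with cells weighed the same, -0.039 without a cell filter and -3.08 with doublets kept, so no direction is drawn. Of 4504 genes measured in all 10 compared classes, 11 were at least 2-fold higher and 3 at least 2-fold lower in every class. These were Xist, Timm23, Isg15, Pck1, Slc13a1, Thoc2l, Sbno2, Tmem254a, Mir6236, Lars2 and Rn18s-rs5, and Ube2s, mt-Nd3 and mt-Nd4. Across genes, which are not independent replicates, Spearman's rho of the log2 ratio with genomic length was 0.118 in T cell-like and 0.0858 in B cell-like cells. Over every deposited barcode, the amino acid transporter Slc7a13 (3146 UMIs in control), Cyp2d9 (762) and Nnt (352) were listed at 0 in FA, and Il17a (1773 UMIs in FA), Acod1 (1190) and Il1a (444) at 0 in control. Whether sex, in which the libraries differed by their sex-linked genes, gives any of these was not tested.

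The tubular injury list was higher in FA proximal tubule-like cells, and free RNA from injured cells may account for part of this. The median gain of the 24 members in B cell-like cells was 0.550 of that in proximal tubule-like cells, past the bound set in advance for free RNA. Members differed: of 20 with a gain in proximal tubule-like cells, B cell-like cells gained at least 0.5 of it for 5, among them Lcn2 and Clu, and under 0.1 of it for 8, among them Spp1, Fga, Fgb and Fgg. The test assumed that B cells do not make these transcripts, which is wrong for some members, such as Vim and Tmsb10. Classes differed too: Lcn2 in FA stood at 47.9 CPM in B cell-like and 7.96 in T cell-like cells, with 0 UMIs in dendritic-like cells. The Lcn2 gain in B cell-like cells, from 51 UMIs in 2.998% of FA cells, is thus not a level shared by all classes. Spp1 was higher in FA in each of these classes. It stood at 95.7 CPM in control and 2596 in FA in B cell-like, 33.2 and 1793 in T cell-like and 39.0 and 496 in dendritic-like cells. Of these FA cells, 91.4%, 84.6% and 54.1% had a Spp1 UMI, so the Spp1 gain was spread over many cells. Response to FA and sex of the animals stay open and were not tested.

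Endothelial-like cells were few in FA, and the tables argue against 3 technical explanations as the whole cause. Over every deposited barcode the median ratio of 12 endothelial markers was 0.0767 (0.0401 to 2.13 over markers), so the transcripts were low before the filter and naming used here. The deposited barcodes held at least 482 UMIs in control and 469 in FA. Barcodes left out before deposit are outside this check. Among cells neither immune nor unnamed the FA share was 0.0348 of the control share, too low for immune growth alone. Among all cells, with doublets kept, the FA share was 0.0593 of the control share. Loss of endothelial cells during tissue dissociation could give the same values and, like a response to FA, stays open and untested.

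Gsdmd was higher in the FA library as a whole, and over the compared classes a different mix of cell classes may account for its difference. Over the 10 compared classes, which held 76.4% of control and 72.3% of FA UMIs, the observed ratio was 2.86; the FA mix at control levels gave 1.02 of its log2 value, a 2.93-fold difference, against 1.05-fold from levels alone. For Gsdme the observed ratio over the same classes was 0.927, so they do not account for its whole-library ratio of 1.71. The FA mix at control levels gave 0.939-fold for Gsdme, and FA levels at the control mix gave 1.87-fold. Unnamed cells and classes seen mainly in FA, among them neutrophil-like and injured tubule-like cells, are outside this test. So are classes seen mainly in control, among them endothelial-like cells, which held 163 Gsdmd UMIs there (36.3 CPM). The Gsdmd log2 ratio was 1.51 over the compared classes and 1.04 over the whole library, so the test covers a different contrast from the whole-library one. Whether FA or the capture of cells set the mix was not tested.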
